A study of Arabidopsis thaliana with 4 samples.

How the data were processed

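Whole-genome bisulfite sequencing was used to read cytosine methylation in Arabidopsis thaliana. Bisulfite converts unmethylated cytosine to uracil and leaves methylated cytosine, so a cytosine read as C counts as methylated. Per the labels, whole plants aged 20 days were grown in a greenhouse at 23 °C with 16 h of light and 8 h of dark, and DNA was taken from plants of a summer month and a winter month. Per the labels' protocols, DNA was sonicated to 100 to 300 bp, amplified with 15 PCR cycles and selected as fragments of 250 to 350 bp. Each season has 2 libraries made from a single DNA sample, sequenced from one end and from both ends. The libraries are therefore technical, and the deposited tables pool them, so each season gives a single value and no spread between plants can be estimated.

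The authors deposited 2 tables, a table per season, which give counts of methylated and of unmethylated reads at each cytosine, with no header. The counts are not normalized. Per the submitters' processing notes the build was TAIR 9. The aligner, the methylation caller and any filter on duplicates or conversion are not given in the sources used here. Both tables list the same 42859589 cytosines of the 5 nuclear chromosomes, with strand and the context CG, CHG or CHH, where H is A, C or T. The summer table holds 155682649 reads over cytosines, a mean of 3.63 and a median of 3 per cytosine. The winter table holds 292237794, a mean of 6.82 and a median of 6. In summer 46.2% of cytosines had 4 or more reads and in winter 67.8%.

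Methylation levels were computed per read, as methylated reads over all reads, and this weighting was fixed before the data were examined. A block jackknife over 1 Mb blocks gave the standard error (SE) of each difference, and Wilson intervals at 95% gave the counting error of each level. Because amplified reads carry no molecular identifiers, intervals and SEs do not cover duplicate reads, and neither covers variation between plants. Pericentromeric regions were set in advance as 12 to 18 Mb on chromosome 1, 1 to 7 Mb on chromosome 2, 11 to 17 Mb on chromosome 3, 2 to 7 Mb on chromosome 4 and 9 to 15 Mb on chromosome 5, and the rest are called arms.

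Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment compared the reads of the summer and winter tables. It compares these read pools, not the seasons. In windows and gene regions, reads are summed over cytosines, so a read that spans several cytosines counts at each of them. The test and the intervals treat these counts as independent, which can make p too small and intervals too narrow. Single cytosines needed 10 reads in each season, an adjusted p up to 0.05 and a difference of 40 points for CG or 20 for CHG and CHH. Windows of 200 bp needed 4 cytosines with 4 reads each, an adjusted p up to 0.01 and 40 points for CG, 20 for CHG or 10 for CHH. Gene regions needed 10 cytosines with 4 reads each, an adjusted p up to 0.01, 20 points for CG, 10 for CHG or 5 for CHH, and the same sign on both strands. Each step was tested on simulated data built from the real depths with 200 changed features. Reads were drawn binomially and independently at each cytosine, with no overdispersion and no duplicate reads. In the real windows overdispersion between the seasons was 1.38 for CG, 1.64 for CHG and 2.22 for CHH. Between the strands it was 2.40 in summer and 3.67 in winter for CG, 1.83 and 2.30 for CHG, and 3.52 and 5.44 for CHH. For CHH the strand values can include real differences, since the strands of a window hold different cytosines. The shares called in the simulation may therefore be too high. Gene bodies simulated with 30 points in CG, 20 in CHG and 10 in CHH were called in 96.5%, 94.5% and 92% of cases among 30858, 30867 and 35184 tested. Windows simulated with 50 points in CG, 40 in CHG and 20 in CHH were called in 74%, 66% and 71.5% of cases among 263895, 304084 and 497868. With 30 points in CG, 20 in CHG and 10 in CHH, windows were called in only 3%, 8% and 19% of cases. Single cytosines were called in 2%, 0.5% and 0% of cases at 50, 40 and 20 points among 143396, 174206 and 621486.

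Gene positions came from a RefSeq table of assembly TAIR10.1, a later name than the build of the files. To check that positions match, the sequence around cytosines was rebuilt from the files and a conserved motif of tRNA genes was sought at its fixed distance from the annotated ends. It was found in 592 of 625 tRNA genes with no shift, in 1 and 2 with a shift of 1 bp to either side and in 0 with a shift of 2 bp. Intervals of 37899 genes were then used to sum reads, and only cytosine positions of the files are printed. The table gives no strand and no transposon annotation. The planned promoter comparison was therefore replaced by the 1 kb flanks on both sides of each gene, and the planned transposon comparison by the 4843 genes annotated as pseudogenes, a class that here includes retrotransposons. The chloroplast genome planned as conversion background was not analysed here, and a stretch of chromosome 2 from 3250001 to 3500000, which holds an inserted copy of mitochondrial DNA, was used in its place. These replacements, and the per-cytosine means in the report beyond the genome-wide ones, were chosen after the data were examined. SEs of differences with the background subtracted treat the background as fixed and leave out its own counting error.

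Genes were named by a rule set in advance. Per context and region it takes up to 3 genes with the largest difference in each direction among those past the threshold. From each of 8 gene lists it adds every member past the threshold or otherwise the 3 members with the largest difference. All 176 genes of the lists were found in the table. Per context it names 3 windows in each direction. The median difference of a list was set against 10000 random lists of the same size matched on mean level. Alternatives varied weighting, coverage minimum, depth, background, strand, window size, thresholds and overdispersion. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9.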

Results

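Cytosine methylation was measured across the genome of 20-day-old Arabidopsis plants in summer and in winter, to ask whether the methylome differs between the seasons under the same greenhouse settings. Each season is represented by a single DNA sample, so no difference below has a replicate check, and every test compares the reads of these samples. Summer gave 155682649 reads over cytosines and winter gave 292237794.

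CG methylation, the mark of gene bodies and transposons, was nearly the same in both seasons once each cytosine counted equally. Over cytosines with at least 4 reads in both seasons the mean level was 20.4% in summer and 20.6% in winter, a difference of 0.161 points (jackknife SE 0.0105). Counted per read, the level was 21.4% in summer (95% Wilson interval 21.36 to 21.39%) and 23.9% in winter (23.92 to 23.95%), 2.56 points higher in winter (SE 0.168). Drawing the same number of reads from both seasons at each cytosine left a difference of 0.169 points. With the background of a mitochondrial insertion on chromosome 2 subtracted, the per-cytosine difference was 0.418 points (SE 0.0118).

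CHG methylation, a mark of transposons and pericentromeric heterochromatin, was lower in winter where it is dense. In pericentromeric regions the mean per-cytosine level was 27.9% in summer and 25.2% in winter, a difference of -2.68 points (SE 0.272). The winter level lay below the summer level in the pericentromeric regions of all 5 chromosomes, from -2.36 points on chromosome 1 to -3.11 points on chromosome 3, and in 58 of 58 pericentromeric bins of 500 kb. Per read the chromosomes did not share a direction, from 0.0713 points on chromosome 1 (SE 0.643) to -0.830 points on chromosome 3 (SE 0.793). In the arms it was 1.90% and 1.79%, a difference of -0.111 points (SE 0.0207). Genome-wide it was 6.01% and 5.49%, a difference of -0.517 points (SE 0.0843). With the background subtracted, the arm difference turned to 0.102 points (SE 0.0213), the genome-wide difference was -0.316 (SE 0.0866) and the pericentromeric difference was -2.54 (SE 0.279). This background, 0.726% in summer and 0.511% in winter, is an upper limit and can subtract too much. In the arm bin starting at 23500001 on chromosome 5, the whole summer CHG level was 0.578%. The sign of the arm difference is therefore unsettled. The genome-wide direction turned when levels were counted per read: 6.75% in summer (interval 6.740 to 6.760%) and 7.08% in winter (7.073 to 7.087%), 0.330 points higher in winter (SE 0.0486). Per read the pericentromeric level was 27.9% and 27.6% (difference -0.304, SE 0.278), and the arm level was 2.13% and 2.22% (difference 0.0981, SE 0.0226).

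CHH methylation was low in both seasons. Mean per-cytosine levels in pericentromeric regions were 5.23% and 5.18% (difference -0.0573 points, SE 0.0246), and in the arms 0.902% and 0.937% (difference 0.0349, SE 0.00200). Per read the pericentromeric direction turned, with 5.38% in summer and 5.74% in winter (difference 0.357, SE 0.0269), and the arms had 1.005% and 1.088% (difference 0.0828, SE 0.00751). Per read the genome-wide level was 1.91% in summer (interval 1.908 to 1.913%) and 2.11% in winter (2.106 to 2.110%), 0.197 points higher (SE 0.0210). The background in the mitochondrial insertion was 0.496% in summer and 0.436% in winter for CHH, 0.726% and 0.511% for CHG, and 0.878% and 0.561% for CG. It is an upper limit on unconverted cytosines, since the nuclear copy can itself be methylated. CHH cytosines there had 2.55 times the depth of the rest of the genome in summer and 2.40 times in winter. With this background subtracted, the per-cytosine CHH difference was -0.000624 points in pericentromeric regions (SE 0.0249) and 0.0946 in the arms (SE 0.00201). These SEs leave out the error of the background, whose winter-minus-summer difference in CHH itself had an SE of 0.0105.

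**Figure D1:**
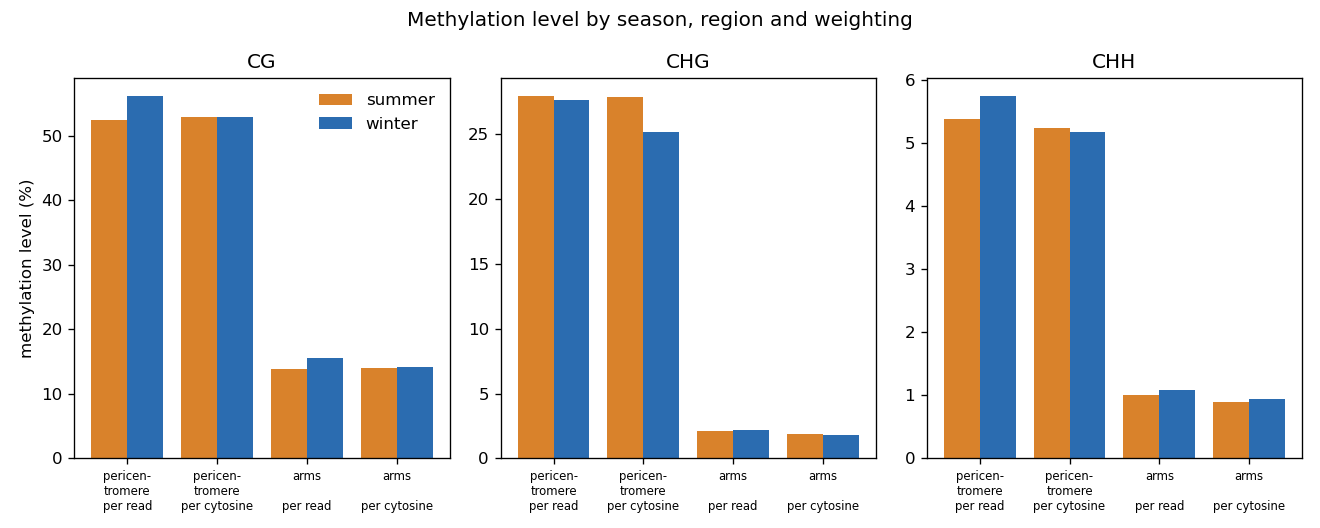
Methylation level in percent (y axis) for summer (orange) and winter (blue) in pericentromeric regions and arms, counted per read or as the mean over cytosines with at least 4 reads in both seasons. Pericentromeric CHG is 27.9% in summer and 25.2% in winter per cytosine, and 27.9% and 27.6% per read.

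The difference between pericentromeric regions and arms was tested by a joint jackknife. Per read the winter-minus-summer difference was 1.95 points larger in pericentromeric regions for CG (SE 0.230) and 0.274 points larger for CHH (SE 0.0283), while for CHG it was -0.403 points (SE 0.283), less than 2 SEs from 0. With each cytosine counted equally it was -0.0628 points for CG (SE 0.0391), -2.57 for CHG (SE 0.276) and -0.0922 for CHH (SE 0.0251).

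**Figure D2:**
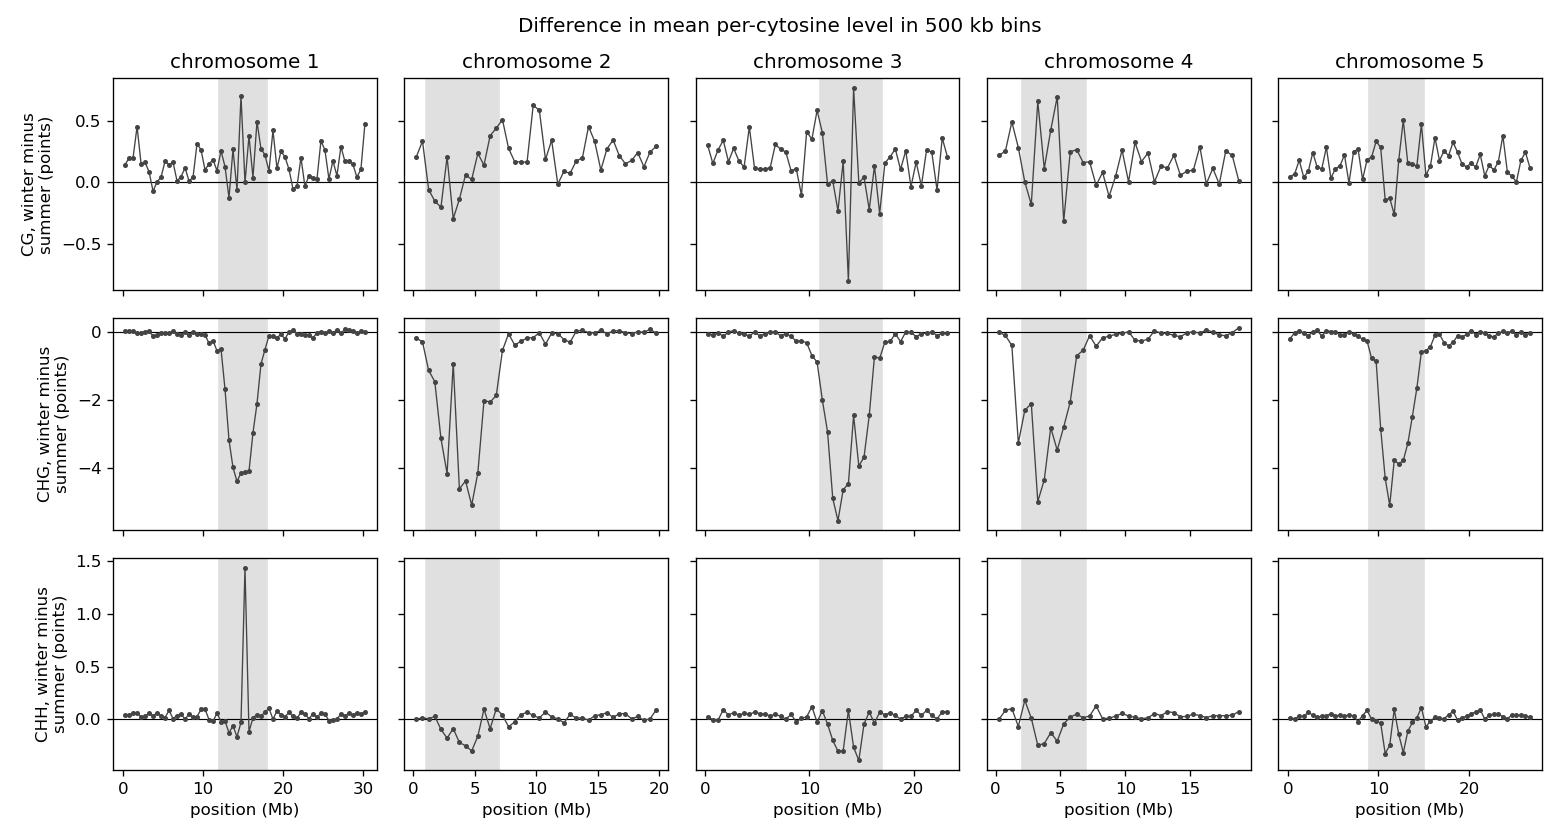
Winter minus summer mean per-cytosine level in percentage points (y axis) in bins of 500 kb along each chromosome (x axis, Mb), with pericentromeric regions in grey. CHG differences are below 0 in all 58 pericentromeric bins, reaching -5.55 points.

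By 3-base context, the pericentromeric CHG difference was shared by CAG, CTG and CCG. The winter level was 0.904 times the summer level at CAG (SE 0.00183), 0.896 times at CTG (SE 0.00215) and 0.934 times at CCG (SE 0.00413). CG contexts had ratios between 0.997 and 1.006. Among CHH contexts, CAA and CTA together had a ratio of 0.971 (SE 0.00415) and the others together 1.018 (SE 0.00510), a difference of -0.0476 (SE 0.00335).

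**Figure D3:**
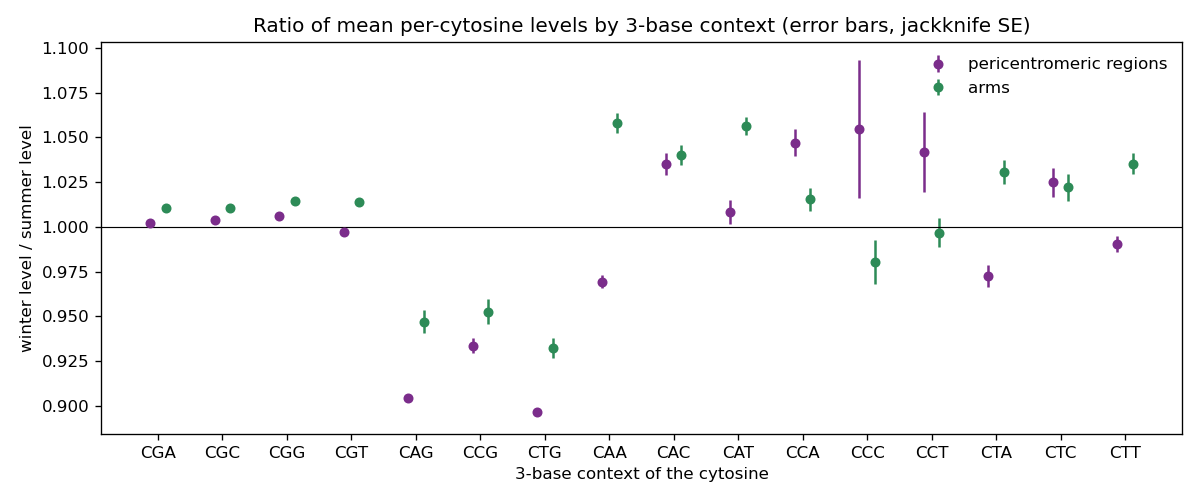
Ratio of winter to summer mean per-cytosine level (y axis) for each 3-base context (x axis) in pericentromeric regions (purple) and arms (green), with jackknife SE bars. CAG, CTG and CCG lie below 1 in both regions, with no background subtracted.

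Pseudogenes, the class that holds retrotransposons here, carried dense CHG methylation and a lower level in winter. Over the 4843 annotated pseudogenes the mean per-cytosine CHG level was 45.0% in summer and 41.0% in winter (difference -4.01, SE 0.171). Per read it was 44.9% and 42.4% (difference -2.54, SE 0.333). Their CG level was 67.5% and 67.7% (difference 0.209, SE 0.0544) and their CHH level 7.59% and 7.51% (difference -0.0801, SE 0.0373). Per read the CG difference was 2.96 points (SE 0.363), and the CHH difference turned to 0.247 points (SE 0.0536). Of 2512 pseudogene bodies with at least 20% CHG methylation, 2145 were lower in winter, with a median difference of -4.87 points. Protein-coding bodies with that much CHG methylation were fewer, 629, and 530 of them were lower in winter. The 16 Sadhu retrotransposons had no clear direction in CHG, with per-cytosine levels of 28.8% and 26.8% (difference -2.03, SE 1.14) and per-read levels of 28.2% and 30.1% (difference 1.90, SE 1.61). Protein-coding genes as a class had a per-cytosine CG level of 15.6% and 15.8% and a CHG level of 1.18% and 1.10%. Per read their CG level was 15.4% and 16.8%, and their CHG difference was -0.00181 points (SE 0.0105). With the background subtracted, their per-cytosine CHG difference turned to 0.134 points (SE 0.0107), and that of pseudogenes was -3.91 (SE 0.174) in CHG and -0.0249 (SE 0.0375) in CHH. The background is an upper limit, so the turn in coding genes can come from subtracting too much.

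**Figure D4:**
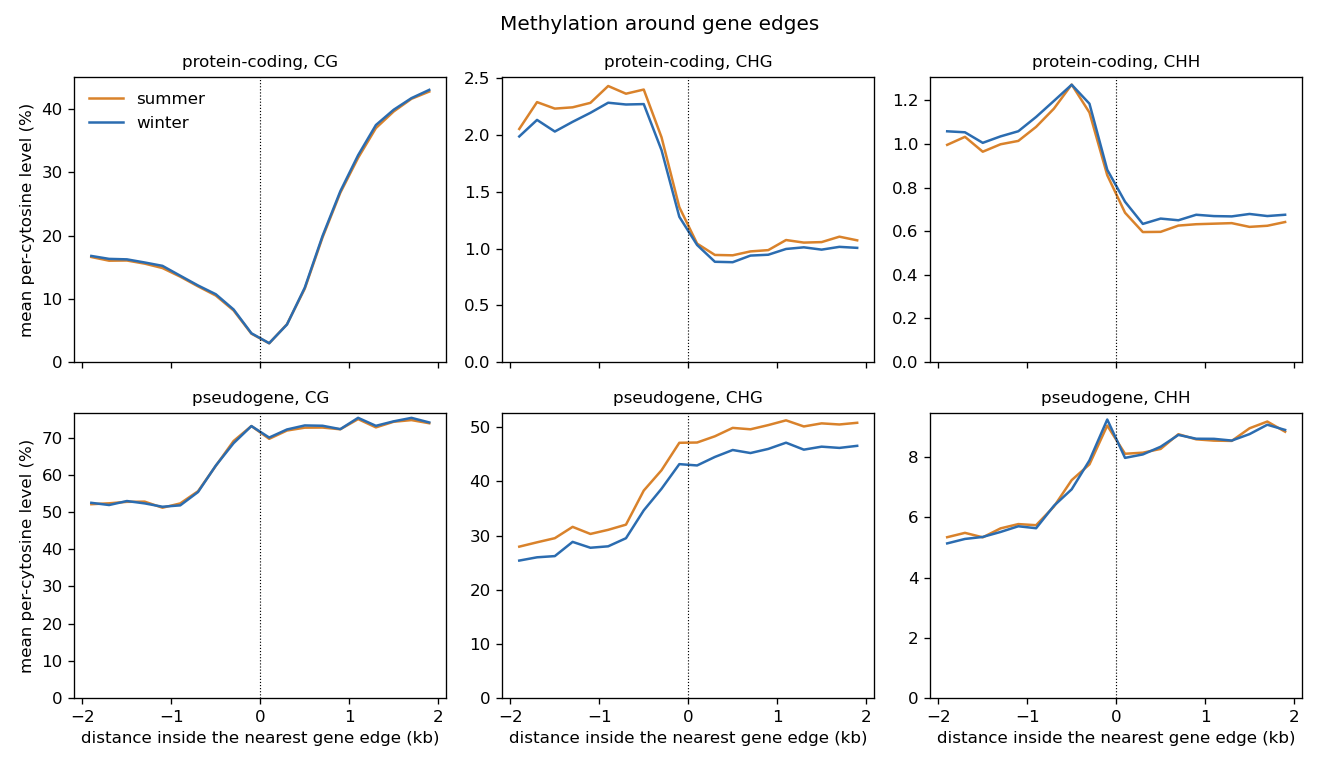
Mean per-cytosine methylation level in percent (y axis) by distance from the nearest gene edge in kb (x axis, positive inside the gene, both edges pooled) for 3248 protein-coding genes and 809 pseudogenes of at least 4 kb, in summer (orange) and winter (blue). At 1.1 kb inside pseudogenes CHG was 51.3% in summer and 47.2% in winter, and inside coding genes CG was 32.3% and 32.7%.

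At single cytosines no difference passed all criteria by Fisher's exact test among 143396 CG, 174206 CHG and 621486 CHH cytosines. An unadjusted p under 0.05 was reached by 1338, 1047 and 1779 of them. At this depth the test could rarely call even a large change, so small or moderate differences at single cytosines were not detectable.

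Among 200 bp windows, 9 of 263895 passed for CG, with 6 higher in winter, 5 of 304084 for CHG, all lower in winter, and 179 of 497868 for CHH, with 77 higher in winter. Across windows, which are not independent replicates, summer and winter levels correlated with r = 0.985 for CG, 0.969 for CHG and 0.864 for CHH, against 0.989, 0.977 and 0.929 when reads were redrawn from pooled levels. All 5 CHG windows lay in pericentromeric regions. Those with the largest differences overlapped the pseudogenes AT4G06556 on chromosome 4 (3473801 to 3474000, 67.5% in summer and 27.8% in winter), AT5G35820 on chromosome 5 (13997201 to 13997400, 75.5% and 49.4%) and AT3G42766 on chromosome 3 (14864401 to 14864600, 80.8% and 54.8%). The largest CG differences were higher in winter near AT5G60840 on chromosome 5 (24475201 to 24475400, 41.2% of 17 reads and 100% of 36), in AT3G05685 on chromosome 3 (1674601 to 1674800, 35.1% and 88.0%) and in XLG1 on chromosome 2, which encodes an extra-large G protein (9996201 to 9996400, 11.1% and 57.3%). They were lower in AT4G19090 on chromosome 4 (10451401 to 10451600, 48.0% of 25 reads and 0% of 52), in AT2G06000 on chromosome 2 (2329801 to 2330000, 52.6% and 5.17%) and beside AT4G03570 on chromosome 4 (1594201 to 1594400, 98.1% and 55.2%). The interval for 0% of 52 reads reaches 6.88%. With at least 1 read per cytosine, the window beside AT4G03570 was the only one of these 6 to pass.

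The largest CHH window differences lay outside annotated genes. Higher in winter were a window on chromosome 4 (6376401 to 6376600, 6.25% of 16 reads and 84.4% of 32), on chromosome 5 (23775401 to 23775600, 19.4% and 92.9%) and on chromosome 1 (15088001 to 15088200, 4.82% of 83 reads and 77.6% of 147, adjusted p = 5.13e-24 by Fisher's exact test). Their counts were summed over 4, 7 and 16 cytosines, so they can come from far fewer reads, which the test does not take into account. Lower in winter were windows on chromosome 3 (11271201 to 11271400, 76.1% and 16.7%) and on chromosome 5 (10165001 to 10165200, 75.7% and 16.9%, and 19001401 to 19001600, 54.3% and 4.26%). After read counts were divided by the overdispersion seen between strands, 0 CG, 0 CHG and 2 CHH windows passed. The strands of a CHH window hold different cytosines, so their overdispersion can include real differences and the CHH count may be too low. With at least 10 reads per cytosine 0 CG, 3 CHG and 10 CHH windows passed.

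Gene bodies that passed in CHG were nearly all lower in winter: 43 of 44 among 30867, of which 32 were pseudogenes. The protein-coding gene AT2G29925 on chromosome 2 went from 41.5% in summer (interval 33.8 to 49.6%) to 20.96% in winter (16.5 to 26.2%) over cytosines from 12755065 to 12755331. AT1G47780 on chromosome 1 went from 58.5% to 40.9% (17594687 to 17595336), and AT1G11590 on chromosome 1 from 54.1% to 36.8% (3892582 to 3894550). The exception was AT2G23945 on chromosome 2, with 8.92% in summer (interval 6.42 to 12.3%) and 21.1% in winter (18.18 to 24.4%) over cytosines from 10185263 to 10186648. The same stretch gave the 3 flanks higher in winter for CHG, those of AT2G23950, AT2G23940 and AT2G07965. Counting cytosines equally, the difference fell short of the minimum at AT2G23945 (8.76 points), AT2G23940 (9.62) and AT2G07965 (9.33). The other 10 CHG flanks that passed were lower, led by the pseudogenes AT2G12505 (55.2% to 22.8%), AT4G06672 (46.5% to 18%) and AT5G28662 (48.4% to 20.0%). With at least 10 reads per cytosine, 3 CHG bodies and 2 flanks passed.

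For CG, 7 of 30858 gene bodies passed, 5 of them higher in winter. AT2G11005 on chromosome 2 had 57.5% in summer and 88.8% in winter, the lncRNA AT2G04655 on chromosome 2 70.6% and 96.4%, and AT1G31163 on chromosome 1 33.3% and 55.6%. Lower in winter were AT1G34317 on chromosome 1, with 42.5% and 14.5%, and AT1G11785 on chromosome 1, with 27.8% and 7.72%. Among 56260 flanks 9 passed. That of AT4G01985 on chromosome 4 had 38.8% and 72.3% (865188 to 866097, adjusted p = 1.57e-12 by Fisher's exact test), that of AT4G10650 36.8% and 64.1%, and that of CYP706A3, a cytochrome P450 gene, 36.2% and 58.6%. Lower in winter were flanks of CSLD6, a cellulose synthase-like gene (67.5% and 36.6%), of SMC5, a gene of chromosome maintenance (33.3% and 10.3%), and of AT4G03570 (96.6% and 75.5%). Counting cytosines equally, the difference fell short of the minimum at AT2G11005 (13.2 points), AT1G31163 (3.98) and AT1G11785 (-14.9), and at the flanks of AT4G10650 (11.1), CYP706A3 (16.2), CSLD6 (-11.5) and SMC5 (-5.73). With at least 10 reads per cytosine no CG body or flank passed.

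For CHH, 13 of 35184 gene bodies passed, 7 of them higher in winter, and 125 of 71182 flanks, 66 of them higher. Regions of neighbouring genes can share cytosines, so these counts can include the same reads more than once. The microRNA gene MIR841a on chromosome 4 had 6.12% in summer (interval 3.54 to 10.4%) and 20.2% in winter (16.2 to 24.9%), AT1G62760 on chromosome 1 13.5% and 25.3%, and the pseudogene AT4G06506 on chromosome 4 6.34% and 14.5%. Lower in winter were AT5G42955 on chromosome 5 (49.3% and 19.8%), the lncRNA AT2G08300 on chromosome 2 (26.7% and 10.7%) and AT1G21928 on chromosome 1 (16.4% and 3.78%). The flank of HR4, a homologue of a powdery mildew resistance gene, had 43.9% of 982 reads in summer and 25.2% of 1816 reads in winter (chromosome 3, 18732095 to 18733016, adjusted p = 9.65e-19 by Fisher's exact test). Flanks of AT5G23250 (36.3% and 8.27%) and AT1G32580 (21.6% and 3.57%) were also lower. Flanks higher in winter were those of AT5G28545 (21.3% and 44.5%), AT1G49490 (19.7% and 42.0%) and AT4G00750 (14.0% and 34.7%). With at least 10 reads per cytosine, 0 CHH bodies and 4 flanks passed.

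Of the gene lists set in advance, only cold response had members past the threshold over all genes, both in CHH flanks, and adjusted over the list alone the count was also 2. The flank of ADS2, a fatty acid desaturase gene, had 17.9% of 385 reads in summer and 33.0% of 667 in winter (chromosome 2, 13374088 to 13374999, adjusted p = 0.000126 by Fisher's exact test). The flank of CAMTA3, a calmodulin-binding transcription activator, had 11.1% of 433 reads and 22.4% of 491 (chromosome 2, 9470225 to 9471216, adjusted p = 0.00292 by Fisher's exact test). Across the 20 genes, 6 had a higher and 14 a lower CHH level in their flanks in winter, with a median of -0.149 points at percentile 5.28 of random lists. Flanks of the light signalling list lay lower among random lists in CHH, with 13 of 20 lower in winter and a median of -0.203 points at percentile 2.72. Those of the loci known to carry regulatory methylation lay high, with 14 of 21 higher and a median of 0.219 points at percentile 97.3. Of the 48 such percentiles computed over lists, contexts and regions, 4 lay below 5 or above 95, where chance gives 4.8. With at least 10 reads per cytosine, 0 members of any list passed.

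In the flowering time and vernalization list none of 30 genes passed. The largest differences of regions tested singly were in CG flanks of FLK (75.9% and 67.3%), VIN3, a gene of the vernalization response (40.2% and 32.2%), and FPA (44.6% and 51.6%). Taken per gene, CG flank differences of the list ran from -10.8 to 3.88 points. Counting cytosines equally, the difference at these single flanks was -2.98 points at FLK, 1.35 at VIN3 and 2.62 at FPA. In the circadian clock list none of 20 passed, and the clock gene LHY had a CG body level of 15.4% in summer and 22.03% in winter (adjusted p = 0.0591 by Fisher's exact test), LNK1 a CG flank level of 36.8% and 26.6%, and ZTL a CHH flank level of 14.1% and 20.5%. Counting cytosines equally, LHY had 15.7% and 17.9%. In the light signalling list none of 20 passed over all genes. Its CG flank at the phytochrome gene PHYC had 49.2% and 26.8% (adjusted p = 0.0199 by Fisher's exact test). Counting cytosines equally it had 49.7% and 45.3%, and a difference of the same sign on both strands was not seen. The CHG flanks of the cryptochrome genes CRY1 and CRY2 had 31.2% and 14.2%, and 66.7% and 55.3%. Adjusted over the list alone, 1 light signalling flank passed, in CHG, and it is not identified here. In the heat response list none of 20 passed, with CG flanks of HSP18.2 at 37.1% and 51.1% and of HSFA3 at 9.68% and 20.5%, and a CHG flank of ROF1 at 35.6% and 45.2%. Counting cytosines equally, HSP18.2 had 36.0% and 38.9%, and the difference was 5.14 points at HSFA3 and -3.32 at ROF1.

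None of 34 genes of the DNA methylation machinery passed. The CG flank of NRPE1, the largest subunit of RNA polymerase V, had 68.8% and 88.7%, that of the chromatin remodeller DRD1 32.0% and 46.2%, and that of SHH1 9.56% and 21.4%. Counting cytosines equally, the difference at DRD1 was 9.26 points. None of 21 loci known to carry regulatory methylation passed. The CHH flank of SDC, an F-box gene silenced by methylation, had 28.7% and 12.8%, the CHG flank of QQS 54.8% and 40.3%, and the CG flank of HDG9 70.7% and 80.9%. None of 15 housekeeping genes passed, with CG body levels of 23.6% and 29.5% at UBC21 and 25.2% and 29.6% at PP2AA3, and a CG flank level of 1.83% and 4.58% at ACT7. Counting cytosines equally, the difference at PP2AA3 was -0.148 points. A difference of the same sign on both strands was not seen at HSFA3, NRPE1, SDC and ACT7. The median CHH flank difference of the housekeeping list, 0.331 points, stood at percentile 99.9 of random lists, although the list was chosen as a reference.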

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

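Alternatives that use the mitochondrial insertion, per-cytosine means within regions, flanks or pseudogenes were chosen after the data were examined; the others were planned. Where not stated otherwise, the cause of a change was not tested. No paired analysis was possible because the tables pool the libraries of each season, and for the same reason leaving out each library in turn was not run. The planned promoter, transposon and chloroplast alternatives were not run, for want of a strand, an element annotation and chloroplast positions. Using either strand alone left the genome-wide differences within counting error.

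Differences in level, winter minus summer in points, depended on weighting and depth. The genome-wide CG difference of 2.56 was 0.161 as a mean over cytosines with at least 4 reads, 0.131 with at least 1 read, 0.169 with reads thinned to equal depth, 1.16 and 1.98 per read with at least 4 and 10 reads, 2.83 with background correction and 2.63 without very deep cytosines. The CHG difference of 0.330 turned to -0.517, -0.634 and -0.565 under the first 3 of these and to -0.124 per read with at least 4 reads, and was 0.576 with at least 10 reads and 0.534 with background correction. The CHH difference of 0.197 was 0.0181, 0.0399 and 0.0353 under the first 3, 0.0958 and 0.363 per read with at least 4 and 10 reads, 0.257 with background correction and 0.193 without very deep cytosines. As means over cytosines with at least 4 reads and background correction together, the differences were 0.418 for CG, -0.316 for CHG and 0.0773 for CHH. In the arms the CHG difference of 0.0981 turned to -0.111 and -0.131 as means with at least 4 and 1 reads and to -0.0228 per read with at least 4, but was 0.102 as a mean with background correction, which turns the arm direction back. That background is an upper limit, so the last turn can come from subtracting too much. In pericentromeric regions the CHH difference of 0.357 turned to -0.0573 and -0.0178 as means with at least 4 and 1 reads and to -0.000624 as a mean with background correction. The pericentromeric excess over the arms, as a mean over cytosines, per read with at least 4 reads and with background correction, was -0.0628, 0.314 and 1.84 for CG and -2.57, -1.41 and -0.461 for CHG, and by the first 2 of these -0.0922 and 0.113 for CHH. As a mean over cytosines and with background correction, the pseudogene difference was 0.209 and 3.08 for CG, -4.01 and -2.44 for CHG, and -0.0801 and 0.303 for CHH, and by both together 0.314, -3.91 and -0.0249.

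Counts of calls followed depth and thresholds. CG sites numbered 1 with at least 20 reads and 4 with no minimum difference, all 4 higher in winter. CG windows numbered 15 at 100 bp, 3 at 500 bp, 0 with at least 10 reads, 27 with a smaller minimum difference, 17 at an adjusted p up to 0.05, 1 with thinned reads and 0 after the overdispersion correction. Under these settings CHG windows numbered 2, 8, 3, 8, 9, 0 and 0, and 11 with at least 1 read. CHH windows numbered 794 with at least 1 read, 10 with at least 10, 292 at an adjusted p up to 0.05, 71 with thinned reads and 2 after the overdispersion correction. With at least 10 reads per cytosine, which leaves fewer cytosines to count, 0 CG, 3 CHG and 0 CHH gene bodies and 0 CG, 2 CHG and 4 CHH flanks passed, and 0 members of the gene lists. A smaller minimum difference gave 58 CG bodies, 53 of them higher in winter, 105 CHG bodies, 2 of them higher, 20 CHH bodies, 11 of them higher, and 22 CG flanks, 15 of them higher. The minimum applied to per-cytosine means gave 2 CG bodies and 3 CG flanks. Flanks of 500 bp gave 3 calls in CG, 2 in CHG and 73 in CHH, 36 of them higher.

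Among named genes that had not passed, counting cytosines equally turned the VIN3 CG flank to 1.35 points, the ROF1 CHG flank to -3.32 and the PP2AA3 CG body to -0.148. Depth limits single cytosines most: simulated changes of 50 points in CG were called in 2% of cases among 143396 cytosines, against 100% of gene bodies among 30858.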

Other observations

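Tests of isolated CHG cytosines, arm windows and reweighted depth were set before their results were seen; tests of the CG ratio, equal depth and the conversion background were chosen afterwards. Outside annotated genes, CHG methylation had a mean per-cytosine level of 13.2% in summer and 12.01% in winter, and long non-coding RNA genes had 2.89% and 2.67%. Per read the direction outside genes turned, with 13.6% and 14.7% (difference 1.13, SE 0.0806), and long non-coding RNA genes had a difference of 0.00907 points (SE 0.0749). With background subtracted, their per-cytosine difference was -0.0134 points (SE 0.0512). The 326 microRNA genes had a CG level of 21.4% in summer and 22.9% in winter (difference 1.60, SE 0.526) per cytosine, and 21.8% and 26.3% per read (difference 4.52, SE 1.21). Of 64737 windows with at least 50% CG methylation in a season and 20 reads in each, 2 were at or below 10% in summer and 4 in winter. For CHG, 4 of 19831 such windows were at or below 10% in winter and 0 in summer. For CHH, 7 of 1134 such windows were at or below 10% in summer and 8 in winter.

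Comparing the strands within a season called more 200 bp windows than comparing the seasons. The plus and minus strands differed in 256 CG windows in summer and 1836 in winter, against 9 between the seasons, and in 438 and 1360 CHH windows, against 179. For CHH this is not a measure of noise alone, since the strands of a window hold different cytosines. Of the 179 CHH windows, 139 had cytosines on both strands and 103 of these had the same direction on both. The 500 kb bin with the highest CHH difference, 1.44 points, starts at 15000001 on chromosome 1, and its 10 called windows were all higher in winter. Their CHH level was 32.7% in summer and 58.1% in winter on the plus strand (323 cytosines) and 29.9% and 39.2% on the minus strand (93 cytosines). These windows were called for their difference, so its size there can be overstated.

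The lower pericentromeric CHG level in winter was weighed against 3 technical explanations. More conversion of methylated cytosines in winter would lower CG in proportion, but the winter CG level was 1.002 times the summer level (SE 0.000725). More unconverted cytosines in summer would raise levels most where methylation is low, so the CG ratio is a weak test of that. The CHG background of the mitochondrial insertion, an upper limit, was 0.726% in summer and 0.511% in winter. Subtracting it left a CHG difference of -2.54 points (SE 0.279). Depth alone is argued against by a difference of -2.46 points (SE 0.267) at 34936 cytosines with the same depth of at least 4 in both seasons. Per-cytosine means already compare the same cytosines in both seasons, so much of this outcome was given and it adds little independent support. A filter on reads with several methylated CHG cytosines would spare isolated ones, but 5935 CHG cytosines with no other within 100 bp on their strand had a ratio of 0.885 (SE 0.00859). A filter that acts over a longer read or read pair, or that also counts CHH cytosines, is not excluded by this. A hypothesis is lower activity at contexts preferred by chromomethylases, which may fit the CAA and CTA ratio in pericentromeric regions, but in 6107 arm windows with over 20% CHG methylation CAA and CTA had a ratio of 1.020 (SE 0.00713) while CHG had 0.923 (SE 0.00496). CHG and these contexts thus went opposite ways there. The outcome set beforehand as against the hypothesis was a CAA and CTA ratio equal to or above that of the other CHH contexts. The arm windows met it, with 1.020 and 1.015, but the difference of 0.00575 (SE 0.00765) was less than its SE. By that rule the arm result went against the hypothesis, by a margin within error. In pericentromeric regions the difference between CAA and CTA and the other CHH contexts was -0.0476 (SE 0.00335). No prediction was set for that value beforehand, so it is not an independent test of the hypothesis. The hypothesis was not settled by these values. With a single DNA sample per season, a difference between plants or between library preparations cannot be told apart from season.

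The higher CG level per read in winter may come from where reads fell. Over the 4735634 CG cytosines covered in both seasons, summer levels weighted by winter depth covered 91.1% of the difference between them, moving from 21.3% to 23.3% against 23.5% in winter. Cytosines covered in a single season were not part of this test. Much of its outcome follows from the small per-cytosine difference over the same cytosines, 0.131 points, so it adds little independent support. At cytosines with 1 read the CG level was 32.9% in summer and 31.6% in winter. At those with 10 reads it was 16.0% and 24.7%.

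CHH methylation in the arms was slightly higher in winter. The CHH level of the mitochondrial insertion gave no sign of a higher unconverted background in winter, with a difference of -0.0595 points (SE 0.0105). That level is only an upper limit on unconverted cytosines, so a higher background in winter is not excluded. A difference between the plants of the seasons was not tested and stays open.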
